A study of Rattus norvegicus and Sus scrofa and Bos taurus with 188 samples.

How the data were processed

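The series profiles DNA methylation, the histone marks H3K4me3, H3K27me3, H3K36me2 and H3K36me3, and RNA in gametes and preimplantation embryos of several mammals. Its labels give 188 samples here, in 90 groups of 4 species, with 62 samples from pig and 52 of RNA. The processed table analysed here belongs to 1 of these groups, the RNA of pig morulae marked PG, a mark that the labels of sister samples use for parthenogenetically activated embryos, which develop from an activated egg with no sperm. The other samples enter no analysis here.

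Per the labels' protocols, the RNA libraries were made with Smart-seq2, a method that copies polyadenylated RNA of a few cells into full-length cDNA. The deposited table holds FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) computed by the authors, per the file headers. It has 1 row per Ensembl transcript, 37571 rows in all, and 1 column of values, in which the authors merged the 4 replicate libraries of the group, as the name of the deposited table says. Whether the reads or the FPKM values of the 4 libraries were merged is not given in the sources used here. The submitters' processing notes name CASAVA 1.8, cutadapt 1.11, Bismark 0.7.0, Bowtie2 2.1.0 and 2.2.5, TopHat2 2.1.1, Cufflinks 2.2.1 and Trim Galore 0.6.4 for all data types together, with no role or order, and the builds rn6, bosTau8 and susScr11. Which of them made the FPKM table, and with which annotation, is not given in the sources used here.

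FPKM divides by transcript length and by the library total. A length that is wrong or very short therefore shifts a gene's value, and the values of different genes are comparable only as far as the lengths and the assignment of reads to transcripts hold. The table shows signs of a fitted assignment in place of counted reads: 4534 rows were above 0 and under 1e-06 FPKM, so no steps of whole reads could be recovered. The depth of the libraries is unknown, and no interval or detection limit that needs read counts is given. The FPKM values of all rows sum to 304889.

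The last 470 rows of the table, from the first mitochondrially encoded gene to the end, were all at 0. They hold 236 gene names, 213 of which have no other row. The run of zeros is 474 rows long, since the 4 rows just before, with KDM5D and SRY among them, were also at 0, and they are read in the same way. A gene of this stretch is described as listed at 0, with no statement on its expression. Such genes counted as below 1 FPKM in the main shares, and an alternative leaves them out.

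Because the 4 libraries share 1 column, there is no spread between replicates. No SD, n or p-value is given, and the tests planned on libraries before the data were examined (a limma fit against 1 FPKM, correlations between libraries, sign tests over libraries) were replaced by values. A gene's value is its highest row, as set before the data were examined, and a gene was called expressed at 1 FPKM or more. The 37 gene lists, the 12 contrasts between lists and the rule for named genes were also fixed before the data were examined. In place of the planned Fisher's exact test, a list's share of genes at 1 FPKM or more was placed among 10000 random lists of the same size, drawn from the other genes and matched on rows per gene in 5 classes. Ties counted by their midpoint, so a list whose share equals an end of the central 95% of random shares can still be singled out. The random lists were not matched on expression, since the level is the outcome. A contrast was the difference between the medians of log2(FPKM + 1) of its lists, placed among 10000 random relabellings of their genes, with an SD over genes from 2000 bootstrap draws. Values outside the central 95%, below the 2.5 or above the 97.5 percentile, were singled out. These percentiles describe this one table, since genes are not replicates, and about 1.85 of the 37 lists would lie outside by chance.

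The rule for named genes took the 4 highest members of each list and up to 3 members whose side of 1 FPKM went against the majority of the list. It also took all members of the imprinted, histone-modifying and DNA-modifying enzyme lists and of the Y-linked list, and the 10 highest genes of the table. Part of the rule, on the most variable genes between libraries, could not be applied. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

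The list procedure was tested on simulated lists of 100 draws each, planted in the 15877 genes of this table. With no planted effect, 3 of 100 lists of 10 genes and 0 of 100 lists of 20 genes lay above the central 95%. With genes raised 4-fold, 11 and 31 of 100 did, and with 16-fold, 52 and 90 of 100. A small constant, larger at 16-fold, was also added to each raised gene, so genes at 0 rose too. These recoveries can therefore exceed those of a pure fold change. A list of about 10 genes within the central 95% can therefore still differ from other genes. For the contrasts with 20 genes per list, 1 of 100 unplanted and 87 of 100 planted differences lay above. The planted difference was 4-fold in FPKM + 1, which also raises genes at 0, so this recovery can exceed that of a 4-fold change in FPKM. Each contrast reported here had at least 1 list of fewer than 20 genes, and recovery at such sizes was not tested for contrasts.

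The gene table supplied as a reference was of rat and was not used for the pig genes, so no positions, transcript lengths or gene classes entered and the planned ratio of X-linked to autosomal genes was not run. Gene names are those of the deposited table, and a list member with no row of its name was not analysed here. Names of the Rfam, pig microRNA or MIR form were treated as small RNAs, which Smart-seq2 does not capture well, and were left out in an alternative. Alternatives set before the data were examined were thresholds of 0.5 and 5 FPKM, only genes at 0.1 FPKM or more, scaling the table to TPM (transcripts per 1e+06), the sum of a gene's rows, a pseudocount of 0.1, means in place of medians and only members above 0. Those chosen after seeing the data were leaving out the trailing rows, the whole run of zeros or the small RNA names, random lists not matched on rows per gene, and the sum of rows for the gene count and the share of the highest genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.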

Results

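The data describe the transcriptome of pig morulae that developed from parthenogenetically activated eggs, and so carry a maternal genome only. The group has 4 Smart-seq2 libraries, which the authors merged into 1 column of FPKM values over 37571 Ensembl transcripts with 15877 gene names. There is no replicate spread for any value below, the depth is unknown, and no second group was analysed, so each comparison sets genes against other genes of the same embryos. Levels are the highest transcript of a gene.

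Of the 15877 genes, 7747 (48.8%) stood at 1 FPKM or more, 5385 lay above 0 and below 1 FPKM, and 2745 were listed at 0. The expressed genes had a median of 6.89 FPKM. Some 3200 genes reached 10 FPKM and 498 reached 100 FPKM. The highest gene was TMSB10, an actin-binding thymosin, at 3719 FPKM. It was followed by the ribosomal protein genes RPS18 at 2888 FPKM and RPS28 at 2832 FPKM, the small RNA methyltransferase gene HENMT1 at 2541 FPKM and the ubiquitin gene UBB at 2534 FPKM. The respiratory chain gene COX7A2 (2126 FPKM), RPS13 (2110 FPKM), RPL10 (2076 FPKM), the translation initiation factor gene EIF1 (1968 FPKM) and RPS15 (1943 FPKM) completed the 10 highest, 5 of which encode ribosomal proteins. Together the 10 took 8.11% of the FPKM total. The number of expressed genes was 4515 at a threshold of 5 FPKM. The last 470 rows, which hold the mitochondrially encoded genes and 236 names in all, were at 0 throughout.

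The lists fixed for the embryo's housekeeping functions separated clearly from random lists. Cytosolic ribosomal protein genes stood at 1 FPKM or more in 44 of 46 cases, with a median of 777 FPKM. With all their rows summed they took 15.2% of the FPKM total. The exceptions were RPL10L at 0.781 FPKM and RPL3L at 0.0934 FPKM, both retrogene or paralogue copies. Nuclear-encoded subunits of oxidative phosphorylation reached 1 FPKM in 64 of 67 cases, with a median of 121 FPKM and, with rows summed, 6.55% of the total. They were led by COX7A2, ATP5MD (1836 FPKM), COX4I1 (1515 FPKM) and COX8A (1308 FPKM). The exceptions among them were COX6B2 at 0.14 FPKM, and COX8H and COX4I2, listed at 0. Both shares lay above all 10000 random lists. All 13 mitochondrially encoded genes were listed at 0 and lie in the trailing rows, so their level is not known from this table. The 9 measured housekeeping genes were all expressed (99.85 percentile), with a median of 43.3 FPKM, among them the histone gene H3F3A at 1599 FPKM, GAPDH at 84.5 FPKM and SDHA at 74.4 FPKM.

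Carbohydrate and lipid metabolism genes had lower medians than the respiratory genes, at 15.1 FPKM for glycolysis and 6.90 FPKM for lipids. Of 14 glycolysis genes 10 (71.4%) reached 1 FPKM, with PGAM1 at 134 FPKM, GAPDH at 84.5 FPKM, ENO1 at 52.3 FPKM and TPI1 at 47.5 FPKM highest, while the phosphofructokinase genes PFKL and PFKP stood at 0.901 and 0.900 FPKM and PFKM at 0.715 FPKM. With rows summed ENO1 came to 106 FPKM, and PFKP (1.07 FPKM) and PFKM (1.41 FPKM) crossed 1 FPKM. That share was at the 89.4 percentile of random lists and went above the central 95% at thresholds of 0.5 FPKM (99.93) and 5 FPKM (99.5), after scaling to TPM (99.8) and with summed rows (98.6). The median of the respiratory subunits exceeded that of the glycolysis genes by 2.95 ± 1.23 (bootstrap SD over genes) on the log2(FPKM + 1) scale. This lay at the 99.99 percentile of relabellings. Of the 18 listed glycolysis genes, 4 were not analysed here. No transcript lengths were used, so the part of short transcripts in this gap was not tested. Of 22 genes of lipid storage and fatty acid oxidation 16 (72.7%) were expressed (98.4 percentile). The lipid droplet coat gene PLIN2 stood at 247 FPKM, the fatty acid binding protein genes FABP5 and FABP3 at 199 and 185 FPKM, and ACADM, a dehydrogenase of fatty acid oxidation, at 97.6 FPKM (186 FPKM summed). The members below 1 FPKM with the highest values were CPT1B (0.614 FPKM), LIPE (0.594 FPKM) and DGAT2 (0.407 FPKM). Among genes at 0.1 FPKM or more alone, the lipid list lay within the central 95% (87.2 percentile).

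Cell division genes were mostly expressed. Of 22 cell cycle genes 19 (86.4%, 99.98 percentile) stood at 1 FPKM or more, or 19 of the 20 outside the trailing rows, with the replication clamp PCNA at 716 FPKM, the mitotic cyclin CCNB1 at 400 FPKM, the helicase subunit MCM7 at 62.7 FPKM (96.7 FPKM summed) and the mitotic kinase PLK1 at 59.7 FPKM. CCND1, a cyclin of the start of the cycle, stood at 0.365 FPKM, and MCM5 and CDC25A were listed at 0 in the trailing rows. Of 16 stress response genes 13 (81.2%, 99.4 percentile) were expressed, or 13 of the 15 outside the trailing rows. The stress transcription factor gene ATF4 stood at 85.6 FPKM, the chaperone gene HSPA5 at 72.6 FPKM, ATF3 at 43.4 FPKM and the cell cycle inhibitor CDKN1A at 20.9 FPKM, while BAX was at 0.497 FPKM and HMOX1 was listed at 0 in the trailing rows. The stress list lay at the 94.0 percentile among genes at 0.1 FPKM or more alone. With no other embryos analysed, these levels have no baseline.

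**Figure D1:**
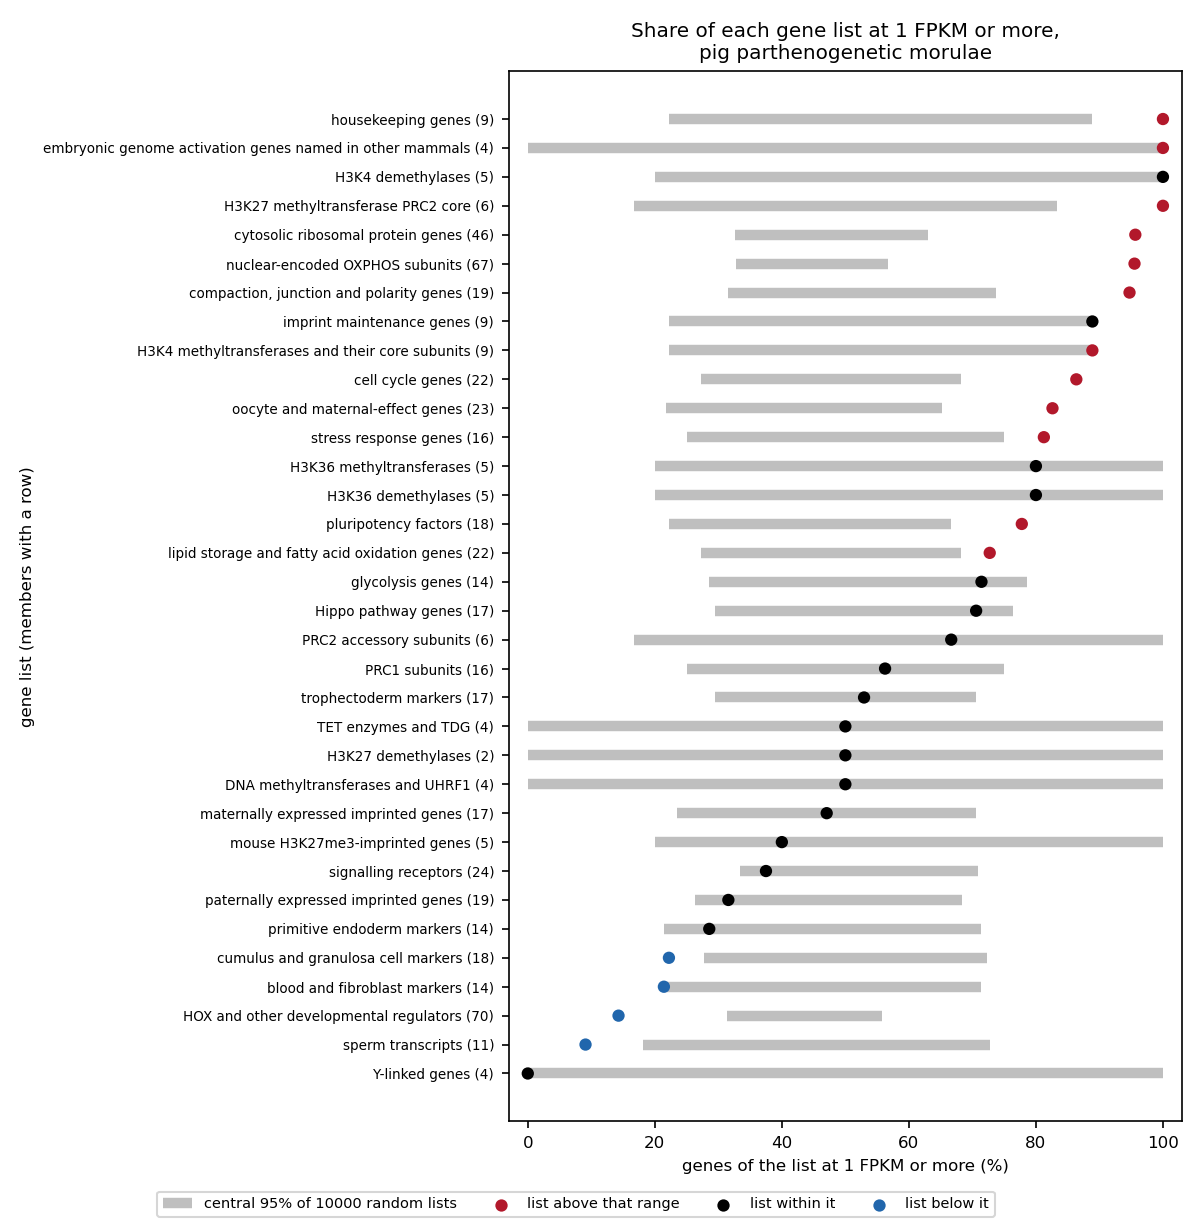
Each row is a gene list, with its number of measured members in parentheses. The point is its share of genes at 1 FPKM or more in percent, and the grey bar is the central 95% of 10000 random lists of the same size. Red points lie above that range, blue points below it and black points within, with ties at the end of a bar placed by their midpoint. The core imprinted lists and the mitochondrial list are not drawn. Ribosomal, respiratory and junction genes sit far to the right of their bars, and the HOX and other developmental regulators (14.3%) to the left.

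The morula is the stage at which blastomeres compact, polarise and begin to separate into lineages, so the lists of these processes were compared. Compaction, junction and polarity genes were expressed in 18 of 19 cases (94.7%), above all 10000 random lists. The polarity gene PARD6B stood at 88.6 FPKM, the tight junction genes CLDN6 and F11R at 56.8 and 50.8 FPKM, and EZR, which links membrane to actin at the apical surface, at 50.2 FPKM. The kinase gene PRKCZ, at 0.318 FPKM, was the one member below 1 FPKM. The adhesion gene CDH1, chosen after its value was seen, stood at 45.2 FPKM. Of 17 Hippo pathway genes 12 were expressed (92.8 percentile), led by TEAD4 at 49.4 FPKM, MOB1A at 24.4 FPKM, YAP1 at 15.5 FPKM and WWTR1 at 14.9 FPKM, with AMOTL2 (0.943 FPKM), VGLL4 (0.686 FPKM) and LATS2 (0.568 FPKM) the highest below 1 FPKM. The Hippo share lay above the central 95% at a threshold of 0.5 FPKM (99.1) and after scaling to TPM (99.6). Signalling receptors were expressed in 9 of 24 cases (37.5%, 8.97 percentile), with KIT at 16.5 FPKM, FZD3 at 7.22 FPKM, LRP6 at 4.99 FPKM and ACVR2A at 4.98 FPKM (9.76 FPKM with its rows summed) highest, and NOTCH1, chosen after its value was seen, listed at 0 in the trailing rows, outside which the share was 9 of 23. Receptors lay below the central 95% at 5 FPKM (0.71) and among genes at 0.1 FPKM or more (0.915).

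Of 18 measured pluripotency genes 14 (77.8%) stood at 1 FPKM or more (99.7 percentile), with a median of 6.55 FPKM. The highest were KLF17 at 85.9 FPKM, ZFP42 at 49.9 FPKM, DPPA5 at 40.4 FPKM and SALL4 at 30.9 FPKM. ETV5 (0.944 FPKM, 1.15 FPKM summed) and TFCP2L1 (0.283 FPKM) were below 1 FPKM, and FGF4 and NODAL, the latter chosen after its value was seen, were listed at 0. SOX2, chosen after its value was seen, stood at 5.36 FPKM, and POU5F1 and NANOG were not analysed here. Among genes at 0.1 FPKM or more alone, the share lay at the 96.3 percentile. Trophectoderm markers were expressed in 9 of 17 cases (52.9%, 58.8 percentile), with PTGES at 225 FPKM, TFAP2C at 194 FPKM, TEAD4 at 49.4 FPKM and the keratin gene KRT18 at 21.5 FPKM. EOMES (0.455 FPKM), DLX3 (0.366 FPKM) and HAND1 (0.275 FPKM) were the highest members below 1 FPKM. The trophectoderm regulators GATA3 and CDX2, chosen after their values were seen, stood at 3.16 and 0.121 FPKM. Primitive endoderm markers were expressed in 4 of 14 cases (28.6%, 8.21 percentile), among them GATA6 at 52.6 FPKM, GATA4 at 2.39 FPKM and RSPO3 at 1.75 FPKM. That share lay at the 1.84 percentile among genes at 0.1 FPKM or more alone.

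The median pluripotency gene exceeded the median primitive endoderm marker by 2.45 ± 0.92 (bootstrap SD over genes) on the log2(FPKM + 1) scale, at the 99.8 percentile of relabellings. Pluripotency against trophectoderm (1.32 ± 1.29, 82.1 percentile) and trophectoderm against primitive endoderm (1.13 ± 0.98, 91.7 percentile) lay within the central 95%. With a pseudocount of 0.1 the differences from primitive endoderm were 3.82 for pluripotency and 2.18 for trophectoderm.

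Oocyte and maternal-effect genes, many of whose transcripts are laid down in the growing egg, were expressed in 19 of 23 measured cases (82.6%, 99.97 percentile), with a median of 6.21 FPKM. The highest were OOSP2 at 179 FPKM, the oocyte linker histone gene H1FOO at 90.3 FPKM, the meiotic kinase gene WEE2 at 65.1 FPKM and the growth factor gene BMP15 at 48.1 FPKM. PABPN1L (0.651 FPKM), ZAR1 (0.461 FPKM) and BNC1 (0.105 FPKM, 0.181 FPKM summed) were below 1 FPKM, and FIGLA, chosen after its value was seen, was listed at 0. Only 4 of the 15 genes listed from embryonic genome activation in other mammals were measured, and all 4 were expressed: EIF1AX at 175 FPKM, KLF17 at 85.9 FPKM, SNAI1 at 27.2 FPKM and CCNA1 at 1.24 FPKM. That share (97.6 percentile) lay within the central 95% in 7 of its 9 alternatives, at an unchanged 100% except at 5 FPKM (75%). The oocyte list lay 2.78 log2 units lower in the median than these 4 genes, within the central 95% of relabellings (4.95 percentile). No egg or earlier stage was analysed here, so RNA stored in the egg cannot be told apart from RNA made in the embryo.

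Enzymes that write and erase the histone marks profiled in the series, with subunits of their complexes, were compared on few genes each. All 6 core genes of PRC2, the H3K27 methyltransferase complex, were expressed (98.9 percentile): the histone-binding subunit genes RBBP4 and RBBP7 stood at 199 and 65.3 FPKM, EED at 92.9 FPKM, the catalytic subunit gene EZH2 at 20.5 FPKM, SUZ12 at 8.86 FPKM and EZH1 at 1.83 FPKM. The summed rows of EZH2 came to 33.7 FPKM. The share stayed at 100%, its ceiling, at 0.5 FPKM, after scaling to TPM and among genes at 0.1 FPKM or more, where more random lists reached it too (97.3, 95.6 and 94.4 percentile). The H3K27 demethylase genes KDM6A and KDM6B stood at 5.00 and 0.966 FPKM, and the summed rows of KDM6B at 1.12 FPKM. The core, with its histone-binding subunits, exceeded the demethylases by 3.46 ± 1.35 on the log2 scale, at the 94.5 percentile of relabellings. With 2 demethylases few relabellings are distinct, and the SD resamples only 2 genes on that side. Of 6 accessory PRC2 subunits 4 were expressed, led by AEBP2 at 36.9 FPKM, MTF2 at 12.03 FPKM (25.5 FPKM summed), JARID2 at 9.92 FPKM and PHF19 at 2.87 FPKM, with PHF1 at 0.214 FPKM and EPOP at 0.0370 FPKM below. Their median lay 2.54 ± 1.73 below that of the core (94.8 percentile). Of 16 PRC1 subunits 9 were expressed (64.1 percentile), led by RNF2 (46.8 FPKM), RYBP (19.7 FPKM) and PCGF6 (18.3 FPKM), with PCGF3 (0.922 FPKM), CBX2 (0.850 FPKM) and PCGF2 (0.642 FPKM) next below 1 FPKM. With rows summed RNF2 came to 98.6 FPKM and PCGF2 crossed the threshold at 1.07 FPKM. The PRC1 share went above the central 95% at 0.5 FPKM (99.1) and after scaling (99.6).

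Among H3K4 methyltransferases and their core subunits, 8 of 9 measured genes were expressed (98.5 percentile). Of the 12 genes listed, the catalytic genes KMT2A, KMT2B and KMT2D were not analysed here. The shared subunit genes DPY30 (160 FPKM), WDR5 (27.5 FPKM), RBBP5 (19.6 FPKM) and ASH2L (9.55 FPKM) were highest. The measured catalytic genes SETD1A (2.14 FPKM), KMT2C (1.82 FPKM) and SETD1B (0.593 FPKM) were low, as were CXXC1 (1.88 FPKM) and MEN1 (1.17 FPKM). The summed rows of ASH2L came to 17.1 FPKM and those of KMT2C to 4.09 FPKM. The call ended at 5 FPKM (81.2 percentile) and, with the share unchanged, among genes at 0.1 FPKM or more (89.6). All 5 H3K4 demethylases were expressed (96.9 percentile, and 98.6 against unmatched random lists), with KDM5B at 18.9 FPKM, KDM1A at 8.75 FPKM, KDM5A at 4.32 FPKM, KDM1B at 4.16 FPKM and KDM5C at 2.34 FPKM. The summed rows of KDM5A came to 9.56 FPKM. Medians of both H3K4 lists differed by -0.76 ± 1.33 (33.9 percentile), and the sign turned with means in place of medians (0.11). Of the H3K36 methyltransferases NSD3 (8.44 FPKM), NSD1 (5.52 FPKM), SETD2 (5.21 FPKM) and ASH1L (2.26 FPKM) were expressed and NSD2 was at 0.717 FPKM. Of the H3K36 demethylases KDM2B (3.09 FPKM), KDM4C (2.91 FPKM), KDM2A (1.71 FPKM) and KDM4A (1.46 FPKM) were expressed and KDM4B was at 0.138 FPKM. With rows summed NSD1 came to 10.1 FPKM, KDM2B to 5.33 FPKM and KDM4A to 2.70 FPKM. Their medians differed by 1.20 ± 0.77 (95.8 percentile), within the central 95%.

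**Figure D2:**
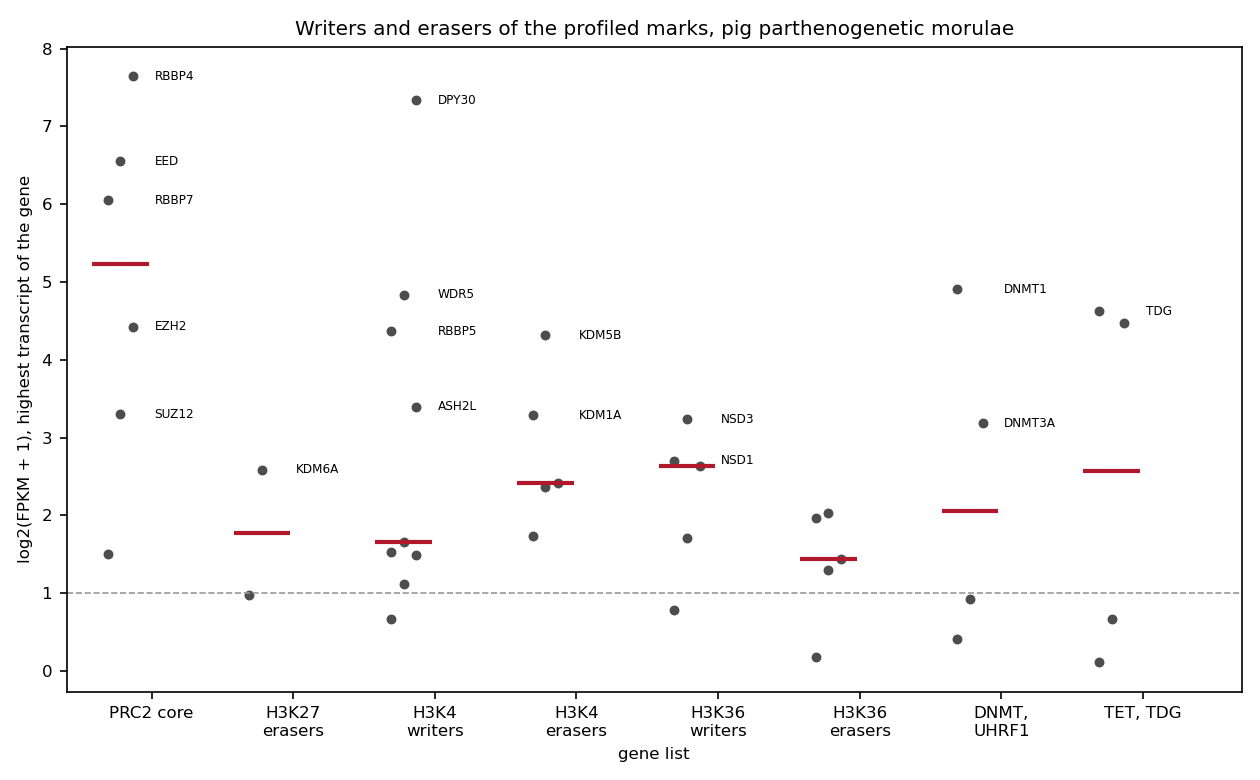
Each point is a gene of a list, on the log2(FPKM + 1) scale of its highest transcript. Red bars are list medians and the dashed line marks 1 FPKM. Names stand beside the higher points where they do not overlap. RBBP4 (199 FPKM) and DPY30 (160 FPKM) are the highest genes drawn.

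For DNA methylation, the maintenance methyltransferase gene DNMT1 stood at 29.0 FPKM and the de novo enzyme gene DNMT3A at 8.09 FPKM, while DNMT3B was at 0.329 FPKM and UHRF1, which recruits the maintenance enzyme, was at 0.896 FPKM. Of the genes of active demethylation TDG (23.6 FPKM) and TET1 (21.1 FPKM) were expressed, and TET2 (0.592 FPKM) and TET3 (0.0800 FPKM) were below 1 FPKM. With summed rows DNMT1 came to 45.3 FPKM, DNMT3B to 0.748 FPKM and TET2, crossing the threshold, to 1.05 FPKM. The shares were 2 of 4 in both lists (35.3 and 58.1 percentile), and their medians differed by -0.52 ± 2.07 (42.0 percentile). Of 9 genes that protect imprints 8 were expressed (97.2 percentile), led by NAA10 at 45.9 FPKM, DNMT1, TRIM28 at 9.66 FPKM and CTCF at 7.71 FPKM, with UHRF1 below 1 FPKM. The summed rows of CTCF came to 19.1 FPKM, above TRIM28 at 9.75 FPKM. The imprint list went above the central 95% at 0.5 FPKM (98.8), after scaling (97.7) and against unmatched lists (99.0).

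Embryos with a maternal genome only would carry no paternal allele of imprinted genes, and the imprinted lists address this. Of 17 measured genes known as maternally expressed 8 (47.1%, 47.3 percentile) stood at 1 FPKM or more: PHLDA2 at 28.9 FPKM, UBE3A at 24.6 FPKM, NAP1L4 at 14.6 FPKM, TFPI2 at 8.79 FPKM, DLX5 at 5.54 FPKM, CDKN1C at 3.24 FPKM, IGF2R at 2.07 FPKM and PPP1R9A at 1.60 FPKM. CALCR, ASB4, TSSC4, GRB10, SLC22A18, KCNQ1 and OSBPL5 lay between 0.0301 and 0.553 FPKM, and ASCL2 and KLF14 were listed at 0. With rows summed CDKN1C came to 5.30 FPKM and GRB10 to 0.225 FPKM. Of 19 genes known as paternally expressed 6 (31.6%, 8.15 percentile) stood at 1 FPKM or more: USP29 at 10.1 FPKM, IMPACT at 6.06 FPKM, NDN at 5.93 FPKM, MEST at 5.43 FPKM, SGCE at 2.57 FPKM and DIRAS3 at 1.21 FPKM. PEG10, INPP5F, PLAGL1, MKRN3 and ZDBF2 lay between 0.160 and 0.561 FPKM. With rows summed IMPACT came to 12.1 FPKM and PEG10 to 0.989 FPKM, and INPP5F crossed the threshold at 1.02 FPKM, which made the share 36.8% (13.2 percentile). DLK1, NNAT, MAGEL2, NAP1L5, RTL1 and INS were listed at 0, as were SNRPN and DIO3 in the trailing rows, outside which the share was 6 of 17 (35.3%, 15.1 percentile). DLK1 and RTL1 lie together in a stretch of 74 consecutive rows at 0, the longest besides the trailing rows, where 16 of 20 names are small RNAs.

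The maternally expressed genes exceeded the paternally expressed genes by 0.28 ± 0.78 in the median, at the 78.5 percentile of relabellings, and by 0.22 without the trailing rows. For the core lists, 3 of 6 maternally and 4 of 11 paternally expressed genes (4 of 10 outside the trailing rows) reached 1 FPKM (52.7 and 17.5 percentile). The core difference was 0.71 ± 0.96 (76.1 percentile) and turned to -0.36 with only members above 0. Neither difference left the central 95%. Which allele was read cannot be seen from FPKM values, and the parental bias of most of these genes comes from other species. Of the genes under H3K27me3-dependent imprinting in mouse, GAB1 (5.27 FPKM, 8.01 FPKM summed) and JADE1 (2.48 FPKM) were expressed and SFMBT2 (0.0630 FPKM), SMOC1 (0.0430 FPKM) and SLC38A4 (0.0186 FPKM) lay below 1 FPKM, a share of 2 of 5 (28.8 percentile).

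**Figure D3:**
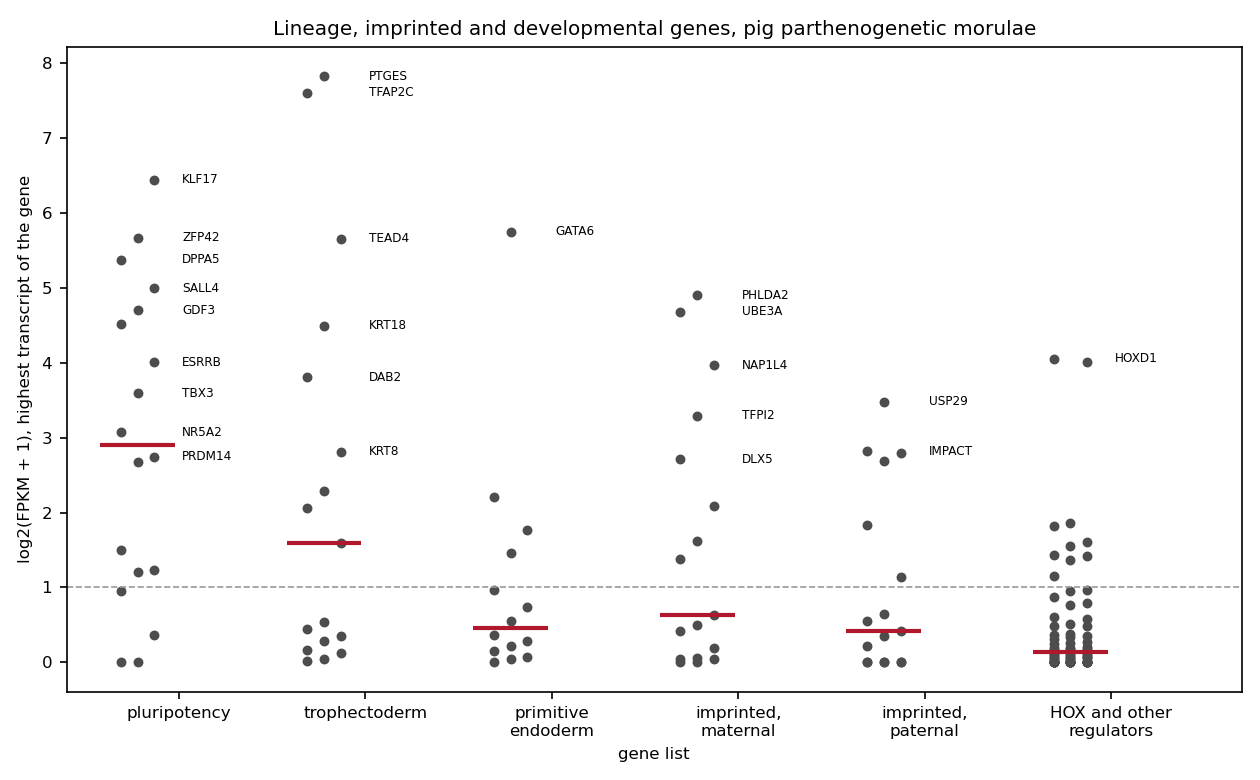
Each point is a gene of a list, on the log2(FPKM + 1) scale of its highest transcript. Red bars are medians and the dashed line marks 1 FPKM. Genes of the trailing rows are left out, and names stand beside the higher points where they do not overlap. The pluripotency median lies above those of the other lists drawn, and most HOX and other developmental regulators lie near 0.

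Regulators of later development lay mostly below 1 FPKM. Of 70 HOX and other developmental genes 10 (14.3%) reached 1 FPKM, below all 10000 random lists, 40 lay above 0 and below 1 FPKM and 20 were listed at 0. HOXD1 (15.6 FPKM) and PAX6 (15.2 FPKM) stood apart from the next members HOXD8 (2.64 FPKM) and HOXD9 (2.54 FPKM). The summed rows of PAX6 came to 26.8 FPKM.

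Markers of other cells that the samples could hold lay mostly below 1 FPKM. Cumulus and granulosa cell markers were expressed in 4 of 18 cases (1.37 percentile): FST at 16.9 FPKM, VCAN at 10.2 FPKM (19.1 FPKM summed), KITLG at 9.15 FPKM (16.1 FPKM summed) and PTGS2 at 1.22 FPKM. Blood and fibroblast markers were expressed in 3 of 14 cases (1.81 percentile): CD74 at 9.46 FPKM, CD14 at 2.38 FPKM and CD68 at 1.32 FPKM. PECAM1, at 0.991 FPKM, was the next highest of that list and crossed the threshold with its rows summed (1.72 FPKM). Of 11 sperm transcripts ODF2 alone was expressed, at 5.05 FPKM (0.645 percentile), AKAP4 and TNP1 were at 0.196 and 0.160 FPKM, and 8 were listed at 0. With a maternal genome only, the embryos would carry no Y chromosome, so a Y-linked share of 0 would follow from the design. Of the Y-linked genes, AMELY stood at 0.174 FPKM and DDX3Y at 0.144 FPKM (0.257 FPKM summed). SRY and KDM5D were listed at 0 within the run of zeros that ends the table, so these zeros alone do not give their level. The Y-linked share of 0 of 4 lay at the 3.25 percentile, and that of 0 of 2 without this run at 8.44. At 5 FPKM and among genes at 0.1 FPKM or more, the cumulus (15.3 and 7.20), blood (3.43 and 4.93) and sperm (9.12 and 13.8) lists lay within the central 95%, and with summed rows the cumulus (3.15) and blood (4.95) lists did. The blood list also did so at 0.5 FPKM (5.97) and after scaling (8.22).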

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

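The alternatives without the trailing rows or the whole run of zeros that ends the table, without small RNA names and with unmatched random lists were chosen after seeing the data, as was the sum of rows for the gene count and the share of the 10 highest genes. No paired analysis was possible because the 4 libraries are merged in 1 column. For the same reason leave-one-out fits, agreement between libraries, limma calls, their pseudocount and filter, and upper-quartile scaling were not run. The X to autosome ratio and the alternatives on short transcripts were not run, since no pig annotation was used here, nor was that without mitochondrial genes, which hold 0. Depth is unknown and limits every low value to an unknown extent. The cause of the changes below was not tested, except that scaling to TPM multiplies all values by 3.28 and so lowers the threshold. Leaving aside the mitochondrial list, whose zeros no setting can move, 16 lists lay outside the central 95% of random lists by the midpoint rule. Of these, the shares of genome activation (100%), H3K4 methyltransferases (88.9%) and blood markers (21.4%) equal an end of that range, so their place outside rests on ties. In every alternative 7 stayed outside (compaction, oocyte, HOX, ribosomal, respiratory, cell cycle and housekeeping genes). Of the 20 lists inside, 12 stayed inside in all. No list changed from one side to the other, and leaving out the trailing rows, or the whole run of zeros, moved none. The Y-linked values below rest on 4 genes, of which 2 lie in that run.

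Shares of genes over the threshold that changed side are given with their percentile. Where a share equals that of the main setting, as for PRC2 core and Y-linked genes, only the random lists moved. At 0.5 FPKM, PRC2 core (100%, 97.3), genome activation (100%, 95.9) and blood markers (35.7%, 5.97) came inside, and Hippo (88.2%, 99.1), PRC1 (87.5%, 99.1), glycolysis (100%, 99.93), imprint maintenance (100%, 98.8) and Y-linked genes (0%, 1.47) went outside. Scaled to TPM, PRC2 core (100%, 95.6), genome activation (100%, 94.0) and blood markers (42.9%, 8.22) came inside, and Hippo (94.1%, 99.6), PRC1 (93.8%, 99.6), glycolysis (100%, 99.8), imprint maintenance (100%, 97.7) and Y-linked genes (0%, 0.885) went outside. At 5 FPKM, H3K4 methyltransferases (44.4%, 81.2), genome activation (75%, 96.2), cumulus (16.7%, 15.3), blood (7.14%, 3.43) and sperm lists (9.09%, 9.12) came inside, and glycolysis (64.3%, 99.5) and receptors (8.33%, 0.71) went outside. Expressed genes numbered 4515 there, against 7747 at 1 FPKM, and between 7641 and 9734 in the other alternatives.

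Among genes at 0.1 FPKM or more, pluripotency (87.5%, 96.3), genome activation (100%, 89.7), PRC2 core (100%, 94.4), H3K4 methyltransferases (88.9%, 89.6), lipid (80%, 87.2), stress (86.7%, 94.0), cumulus (44.4%, 7.20), blood (37.5%, 4.93) and sperm lists (33.3%, 13.8) came inside, where the random lists hold fewer low genes by construction. Primitive endoderm (36.4%, 1.84) and receptors (42.9%, 0.915) went outside. With summed rows, genome activation (100%, 97.4), cumulus (27.8%, 3.15) and blood lists (28.6%, 4.95) came inside and glycolysis (85.7%, 98.6) went outside. Genome activation also came inside without small RNA names (100%, 97.2) and with unmatched lists (100%, 97.2), where H3K4 demethylases (100%, 98.6) and imprint maintenance (88.9%, 99.0) went outside.

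Both contrasts outside the central 95% of relabellings stayed there in all 7 alternatives. Pluripotency minus primitive endoderm was 3.82 and trophectoderm minus primitive endoderm 2.18 with a pseudocount of 0.1, which spreads low values by construction. The core imprinted difference turned to -0.36 with only members above 0, which drops the genes listed at 0. The H3K4 difference turned to 0.11 with means. With summed rows 32 of the genes above 0 that the naming rule takes moved by over 1.5 times and 158 did not, and the 10 highest genes took 8.39%.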

Other observations

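Gene families of at least 30 names, grouped by the letters their symbols start with, were described after the data were seen. Of 39 such families, 14 had a share at 1 FPKM or more above the central 95% of random lists of other genes and 12 had a share below, against 50.6% of all names that are not small RNAs. The families at the top and at the bottom are described by name only. Translation initiation factors (EIF) were expressed in 41 of 42 cases, with a median of 66.2 FPKM. Mitochondrial ribosomal proteins (MRPL) followed with 37 of 38 and a median of 57.4 FPKM. RNA-binding motif genes (RBM) were expressed in 27 of 30 cases. UBE names, mostly ubiquitin-conjugating enzymes, were expressed in 30 of 34 and DEAD-box helicases (DDX) in 28 of 33. The highest UBE gene was UBE2C, which acts in mitotic exit, at 526 FPKM, and the highest DDX gene was DDX5 at 432 FPKM. Names starting with CDC, mostly cell division cycle genes, were expressed in 25 of 30 cases. Names starting with CEP, mostly centrosomal proteins, were expressed in 26 of 32 cases, at a lower median of 1.92 FPKM.

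Among the families below, olfactory receptors (OR) were expressed in 2 of 97 cases, the highest being OR8S1 at 1.63 FPKM. Names starting with COL, mostly collagens, were expressed in 3 of 31 cases, interleukins and their receptors (IL) in 12 of 70, orphan G protein-coupled receptors (GPR) in 14 of 67, and keratins (KRT) in 8 of 37, with KRT18 highest at 21.5 FPKM. Families with leucine-rich repeat (LRRC, 16 of 60), TRIM (19 of 52) and KIAA names (12 of 33) were among the others below. Solute carriers (SLC), the largest family, were expressed in 137 of 337 cases (40.7%, 0.005 percentile), but their highest member, the mitochondrial phosphate carrier SLC25A3, stood at 724 FPKM. Zinc finger genes (ZNF) were expressed in 145 of 251 cases (57.8%, 97.4 percentile), within the central 95%.

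All tests of explanations below were chosen after the results were seen. The first pattern is the 470 trailing rows at 0. They start with the mitochondrially encoded genes and hold genes that dividing cells use, such as HSP90AA1, DYNC1H1, TUBB4B and MCM5, chosen after their values were seen. Stretches of 470 consecutive rows lying wholly before it held at least 324 rows above 0, with a median of 395. For MCM5, a lack of transcription is hard to square with its partners in the replicative helicase, since all 5 (MCM2, MCM3, MCM4, MCM6 and MCM7) stood between 5.03 and 62.7 FPKM. Whether the sequences were left out when transcripts were quantified was not tested and stays open for the stretch, as does the expression of its other genes.

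The next pattern is the small gap between maternally and paternally expressed imprinted genes in embryos with no paternal genome. On the log2 scale the difference was 0.28 with the trailing rows and 0.22 ± 0.81 (bootstrap SD over genes, interval from -0.95 to 2.15) without them. Neither value is set apart from 0, so whether there is a gap at all, with or without those rows, stays open. The absence of a paternal genome cannot be told apart from genes that are unimprinted or silent at this stage, since the difference without these rows lay at the 72.8 percentile of relabellings and fertilised morulae were not analysed here. The paternally expressed genes at 1 FPKM or more, such as USP29, IMPACT, NDN and MEST, are the ones to compare with fertilised embryos.

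Single transcripts with very high values are given without a test, and were chosen after their values were seen. MYO5A, a myosin motor gene, was listed at 1444 FPKM on 1 of its 7 rows, and the next row stood at 6.01 FPKM, a ratio of 240. That was the highest ratio among the 33 genes with 5 rows or more and 100 FPKM or more, whose median was 6.43, and CCPG1 stood at 867 against 5.73 FPKM, a ratio of 151. HENMT1 stood at 2541 FPKM with 1 row.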
